A study of Canis lupus familiaris with 6 samples.

How the data were processed

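RNA from 6 cryopreserved canine cutaneous tumours was measured on a canine oligonucleotide array, 1 array per tumour, with 3 fibrosarcomas and 3 peripheral nerve sheath tumours (PNST). Per the labels' protocols, frozen specimens were macrodissected for tumour content, total RNA was extracted with a column kit and checked for integrity, and biotin-labelled cRNA was made with a 3' in vitro transcription kit, so that signals come mainly from the 3' ends of transcripts. The deposited values are log2 probe set summaries, and per the submitters' processing notes the tools were RMA and Partek, with versions not given in the sources used here. RMA corrects the background, makes the arrays' distributions equal and combines the probes of a probe set. The quantiles of the 6 arrays nearly coincided, with medians of 6.02 to 6.04. Making distributions equal removes any overall difference in transcript amount between tumours, and RMA compresses differences of dim probe sets, so folds near the background are understated. Scanner files and detection calls were not used here.

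The value table held 43035 probe sets, of which 111 were controls and were left out of the tests, leaving 42924. Gene names came from the platform's annotation, updated through gene identifiers to the symbols of the dog assembly UU_Cfam_GSD_1.0. With it, 29254 probe sets had 1 gene symbol (27680 of them matched by identifier), 439 had several and were not named, and 13231 were unnamed here. The files used name no genome build for the probe sets, so no coordinates are given, and the reference was used only for names and for which genes are neighbours. A probe set was tested if it lay above its array's 40th percentile on at least 3 of the 6 arrays, which left 26294 probe sets and 10772 genes. Arrays have no read depth, and the number of arrays limits the precision.

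Groups came from the labels. Replicate numbers were taken from the sample titles and do not state a shared origin. Each probe set was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), and a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets was called past the threshold. Differences are PNST minus fibrosarcoma, on the log2 scale. Because no detection calls were used, the array's 40th percentile (5.39 to 5.42) stood in for the background. Where 1 or more arrays of the dimmer group lay under it, the fold is given as "at least", from the brighter group's mean against the mean of, per array, the higher of that percentile and the probe set's own value. Differences on the log2 scale are given as measured, values under that percentile included. On simulated arrays with the means and spreads of the 26294 probe sets and 200 changed probe sets in each of 5 runs, the test recovered 21.2% of changes of 1 on the log2 scale, 63.2% of changes of 2, 75.2% of changes of 3 and 91.6% of changes of 4, and 4.41% of its calls were false. The comparison itself gave 1453 calls, and with more changes the adjustment sets a looser limit on p. These shares therefore describe a comparison with 200 changes and do not carry over to the real one.

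For gene lists, each gene was represented by its tested probe set with the highest mean. The 38 lists of pathway and cell type genes were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives listed below. Lists with at least 5 measured members, 36 in number, were tested with camera in limma with its preset correlation of 0.01 and adjusted over the lists. The erythrocyte list, with 2 measured members, and the sex-linked list, with 0, were not tested. Members were also tested one by one, with the adjusted p over all probe sets and adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives. The text names the 12 genes with the largest differences in each direction among those past the threshold with non-overlapping groups, up to 4 members with the smallest p of each list that passed and of the Schwann cell, neuronal, Hedgehog, perineurial, pericyte and fibroblast matrix lists whatever their test gave, and, where measured, markers chosen beforehand, among them S100B, SOX10, NGFR, GFAP, NES, ERBB3, PMP22, MKI67 and PDGFRA. MKI67 had no probe set named here. A gene with several called probe sets counted once, by the brightest.

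The alternatives were no filter, a filter at the 60th percentile, quantile normalization applied again, median centring, eBayes with trend and robust settings, array weights, no moderation, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. No batch, scan date or slide was used, so an effect of such a batch can be neither seen nor excluded. Comparisons of the 6 arrays over all splits into 3 and 3 are limited to 10 splits.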

Results

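Transcript levels were measured in 6 frozen canine skin tumours, 3 fibrosarcomas and 3 peripheral nerve sheath tumours (PNST), with 1 oligonucleotide array per tumour. Fibrosarcomas are malignant spindle cell tumours classed with fibroblasts, and PNST are spindle cell tumours classed with the cells around peripheral nerves. Per the labels, each specimen was trimmed to regions rich in tumour cells before RNA was extracted. The deposited log2 values ran from 2.45 to 14.93 over 43035 probe sets, with array medians between 6.02 and 6.04. Arrays have no read depth, so the number of arrays limited the precision. The labels do not say whether the specimens came from separate dogs, so p-values measure only the spread between these specimens. The 3 PNST correlated at Pearson's r of 0.972 to 0.980 with each other, the 3 fibrosarcomas at 0.951 to 0.963, and tumours of different types at 0.929 to 0.940, all across probe sets, which are not independent replicates. The first principal component held 52.0% of the variance and parted the tumour types. The median SD of a probe set was 0.283 among fibrosarcomas and 0.225 among PNST.

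The study asked how the whole transcriptome differs between these tumour types and whether neuroectodermal marker genes part them. Many of the widest differences were in single genes that were bright in one tumour type and near the background in the other. Others lay above the background in both types, such as *GPC3* (6.40 in fibrosarcoma), *ABI3BP* (8.27 in fibrosarcoma) and *CLU* (8.94 in PNST). *HHIP*, which encodes a protein that binds and blocks Hedgehog ligands, was at least 70.7-fold higher in PNST, *GPC3*, the proteoglycan glypican-3, was 114-fold higher, and *CLEC3B*, which encodes tetranectin, was at least 91.4-fold higher. In the other direction, *FHL2*, a LIM-domain protein, was at least 39.3-fold higher in fibrosarcoma and *SEPTIN6*, a septin, at least 32.7-fold higher. Of 26294 probe sets tested, 1453 (5.53%) passed an adjusted p of 0.05 in limma, 766 of them higher in PNST and 687 higher in fibrosarcoma. Those higher in PNST named 395 genes and those higher in fibrosarcoma 324 genes, with 0 genes called in both directions, and 449 of the calls had no gene name here. The 3 arrays of each group did not overlap at any of the 1453, against 30.2% of all tested probe sets and 10% by chance. With 3 arrays per group this threshold leaves almost no room for overlap, so that result follows from how the calls were chosen and adds no support. With values under the background level taken as they are, differences reached 2-fold in 1260 of the calls, 4-fold in 583 and 16-fold in 74, of which 47 were higher in PNST. As a description without correction, 1965 probe sets were at least 2-fold apart at an unadjusted p under 0.01. The number of calls fell to 906 without fibrosarcoma 2, 718 without fibrosarcoma 3, 540 without PNST 1, 295 without PNST 2 and 296 without PNST 3. Of these calls, 690, 582, 471, 278 and 286 in the same order were among the 1453, and the rest were new. Without fibrosarcoma 1 there were 1240 calls, 835 of them among the 1453. The number of calls was 76 when each probe set's own variance was used without moderation.

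The 12 genes with the largest differences in each direction were ranked by the log2 values as they are, whether or not the dimmer tumour type lay above the background level, so the folds given below do not follow that rank. Among the 12 towards PNST, the *HHIP* probe set read 11.55 ± 0.87 in PNST and 3.99 ± 0.42 in fibrosarcoma (mean ± SD of log2 values, n = 3 each; adjusted p = 0.0029). *GPC3* read 13.23 ± 0.48 against 6.40 ± 0.75 (adjusted p = 0.0030) and *CLEC3B* 12.13 ± 0.38 against 5.49 ± 0.38 (adjusted p = 0.0012). *KRT7*, a keratin of simple epithelia, was 37.0-fold higher in PNST, *LGALS4*, a galectin, 30.2-fold, *ABI3BP*, an extracellular matrix protein, 26.3-fold, and *ITGAE*, the integrin alpha E chain, 25.4-fold. For genes under the background level on 1 or more fibrosarcoma arrays only a bound could be given. *ROBO2*, a receptor for Slit guidance cues, was at least 35.8-fold higher, *JAKMIP2* at least 30.9-fold, *MYOC*, the secreted protein myocilin, at least 39.9-fold, *PON3*, a paraoxonase, at least 21.7-fold and *RFPL4B* at least 7.13-fold. *MYOC* varied widely among the PNST, at 8.38, 12.82 and 10.97. For 6 of these 12 genes leaving out 1 array moved the fold or bound by over 1.5 times: *KRT7* to 23.4 without PNST 2, *LGALS4* to 55.4 without fibrosarcoma 2, *ITGAE* to 15.1 without PNST 1, *MYOC* to 89.9 without PNST 1 and 19.3 without PNST 2, *PON3* to 12.1 without PNST 1 and 48.4 without PNST 2, and *RFPL4B* to 10.8 without PNST 1 and 3.62 without PNST 3.

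Among the 12 with the largest differences towards fibrosarcoma, *FHL2* read 10.70 ± 0.69 in fibrosarcoma and 4.30 ± 0.10 in PNST (n = 3 each; adjusted p = 0.0023), and *SEPTIN6* 10.43 ± 0.67 against 5.10 ± 0.17 (adjusted p = 0.0030). *FNBP1L*, a membrane-bending adaptor of the actin cytoskeleton, was 27.8-fold higher in fibrosarcoma with little spread in either group, at 10.84 ± 0.19 against 6.04 ± 0.14 (adjusted p = 0.00089). *CLU*, the secreted chaperone clusterin, was 18.5-fold higher, *CLMP*, a cell adhesion molecule, at least 22.4-fold and *PTPRG*, a receptor tyrosine phosphatase, at least 12.9-fold. *ANK3*, which encodes ankyrin-G, was at least 19.1-fold higher, the kinase gene *MARK1* at least 16.9-fold and the adaptor gene *SHC3* at least 12.8-fold. The zinc finger gene *PLAGL1* was at least 10.3-fold higher, *STXBP5*, which encodes tomosyn, at least 9.94-fold, and *NT5E*, the ectonucleotidase CD73, at least 7.01-fold. Bounds of 4 of these 12 moved by over 1.5 times when 1 array was left out: *ANK3* to 8.76 without fibrosarcoma 1 and 38.1 without fibrosarcoma 2, *NT5E* to 11.98 and 4.24 without the same arrays, *SHC3* to 19.9 without fibrosarcoma 1 and *CLMP* to 39.5 without fibrosarcoma 3. Of the 24 genes named here, 20 had other tested probe sets, which all went the same way for 18. The exceptions were *ITGAE*, where another probe set differed by -0.18 on the log2 scale, and *NT5E*, where the other differed by 0.21. The sizes often differed: *SHC3* had a second probe set at only -0.52, *CLEC3B* 1 at 3.77 against 6.64, *FHL2* 1 at -3.43 against -6.40, *KRT7* 1 at 1.60 against 5.21, and *ROBO2* 3 at 1.37 to 3.16 against 5.39. Of the 24, 12 kept an adjusted p under 0.05 without each array in turn: *HHIP*, *GPC3*, *CLEC3B*, *ABI3BP*, *FHL2*, *SEPTIN6*, *FNBP1L*, *MARK1*, *CLU*, *PTPRG*, *PLAGL1* and *STXBP5*. By array left out, 20 kept it without fibrosarcoma 1, 19 without fibrosarcoma 2, 17 without fibrosarcoma 3, 18 without PNST 1, 15 without PNST 2 and 14 without PNST 3.

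**Figure D1:**
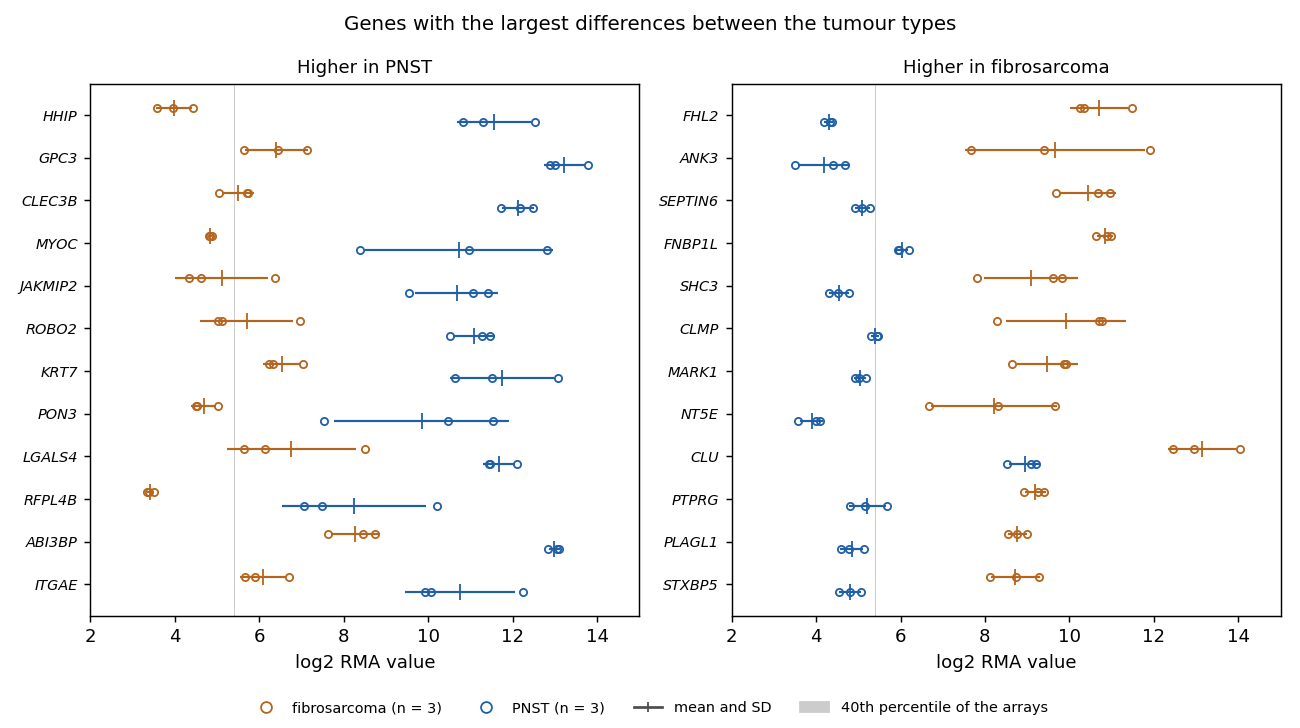
Log2 RMA value (horizontal axis) of the 12 genes with the largest difference in each direction, 1 circle per tumour, with bars for the mean and SD of the 3 tumours of a type and a grey band for the 40th percentile of the arrays (5.39 to 5.42). The tumour types do not overlap for any of the 24 genes, as the rule that chose them requires, and *MYOC*, *PON3* and *ANK3* spread widest within the brighter type.

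Of the lists that passed camera with its preset correlation, Hedgehog alone was shifted towards PNST; it rested on a few of its members and did not pass with an estimated correlation (adjusted p = 0.45). Of 12 measured members, 3 rose in PNST, 0 fell and 9 did not pass (4 rose when adjusted over the list alone). *GLI1*, a transcription factor that is itself a target of the pathway, rose 10.9-fold (9.55 ± 0.09 against 6.10 ± 0.19, n = 3 each; adjusted p = 0.0014), *HHIP* rose as given above, and *BOC*, a co-receptor for Hedgehog ligands, rose 5.37-fold (adjusted p = 0.034), although its second probe set differed by only 0.63 against 2.43 on the log2 scale and did not pass. *CDON*, a related co-receptor, differed by 2.45 on the log2 scale (adjusted p = 0.060), while *PTCH1*, the receptor and a further target of the pathway, differed by 0.05 (adjusted p = 0.86) at 5.73 in PNST, close to the background level. The median difference of the list was 0.36 and the mean 1.38. The list's shift had an adjusted p of 0.0058 in camera with its preset correlation. *BOC* did not pass without any one of fibrosarcoma 2, fibrosarcoma 3, PNST 1, PNST 2 and PNST 3 (adjusted p up to 0.12), while *GLI1* passed without each array in turn.

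Among classical markers of Schwann cells, the glia of peripheral nerve, *S100B*, *SOX10* and *PMP22* overlapped between the tumour types. Of 20 measured members of the Schwann cell and neural crest list, 0 rose and 0 fell in limma, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05. In 3 of the 20 the tumour types did not overlap (against 30.2% of all tested probe sets and 10% by chance), *ETV1*, *GLDN* and *EGR2*, the last named after its values were seen, all 3 lower in PNST. *S100B*, a calcium-binding protein used as a Schwann cell stain, read 7.11 ± 0.39 in PNST and 6.08 ± 1.81 in fibrosarcoma (adjusted p = 0.54), and *SOX10*, a neural crest transcription factor, 6.36 ± 0.06 against 6.39 ± 0.36 (adjusted p = 0.94). *S100B* lay under the background level on fibrosarcoma 3 (4.17). *SOX10* read only 6.08 to 6.79 over all arrays, not far above the background level of 5.39 to 5.42, so a difference in it could be missed. *PMP22*, a myelin protein, was bright in both, at 12.06 ± 0.67 and 11.71 ± 0.27 (adjusted p = 0.63). *ETV1* differed by -3.32 (adjusted p = 0.073), *GLDN*, gliomedin, with 1 PNST array under the background level, by -2.96 (adjusted p = 0.15), *CRYAB* by -1.64 (adjusted p = 0.34) and *GAP43*, a growth cone protein, by 3.45 (adjusted p = 0.22), with PNST values of 7.98, 12.46 and 13.39. *GFAP*, *NGFR* and *ERBB3* lay under the filter and were not tested. *GFAP* stayed under 5 on every array, whereas fibrosarcoma 3 read 8.40 for *ERBB3*, against 4.15 or less in the other tumours, and 8.30 for *NGFR*, against 6.34 or less. The list's shift did not pass (median -0.39; adjusted p = 0.24 in camera, 0.56 with an estimated correlation).

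Neuronal genes rose in part. Of 17 measured members of the neuronal cytoskeleton, synapse and neurotrophin receptor list, 3 rose in PNST, 0 fell and 14 did not pass, with the same 3 when adjusted over the list alone. *PRPH*, the intermediate filament peripherin of peripheral neurons, rose 7.65-fold (11.11 ± 0.03 against 8.18 ± 1.02, n = 3 each; adjusted p = 0.031), *ELAVL3*, a neuronal RNA-binding protein, at least 2.55-fold (adjusted p = 0.025), and *ENO2*, neuron-specific enolase and a member of the hypoxia and glycolysis list too, 2.66-fold (adjusted p = 0.036). The 2 other *ENO2* probe sets differed by only 0.45 and 0.62 on the log2 scale and did not pass. *NES*, the intermediate filament nestin, differed by -0.51 (adjusted p = 0.17). The shift of the list did not pass in camera (median 0.28; adjusted p = 0.14, and 0.50 with an estimated correlation), while fry, which asks only whether the members move one way on balance, gave an adjusted p of 0.026. The mean level of the list was 7.76 in PNST 1, close to the 7.57 of fibrosarcoma 3, against 8.18 in PNST 2 and 8.39 in PNST 3. *ELAVL3* did not pass without any one PNST array (adjusted p up to 0.097), and *PRPH* and *ENO2* passed only without fibrosarcoma 1 (adjusted p up to 0.11 and 0.12 otherwise).

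**Figure D2:**
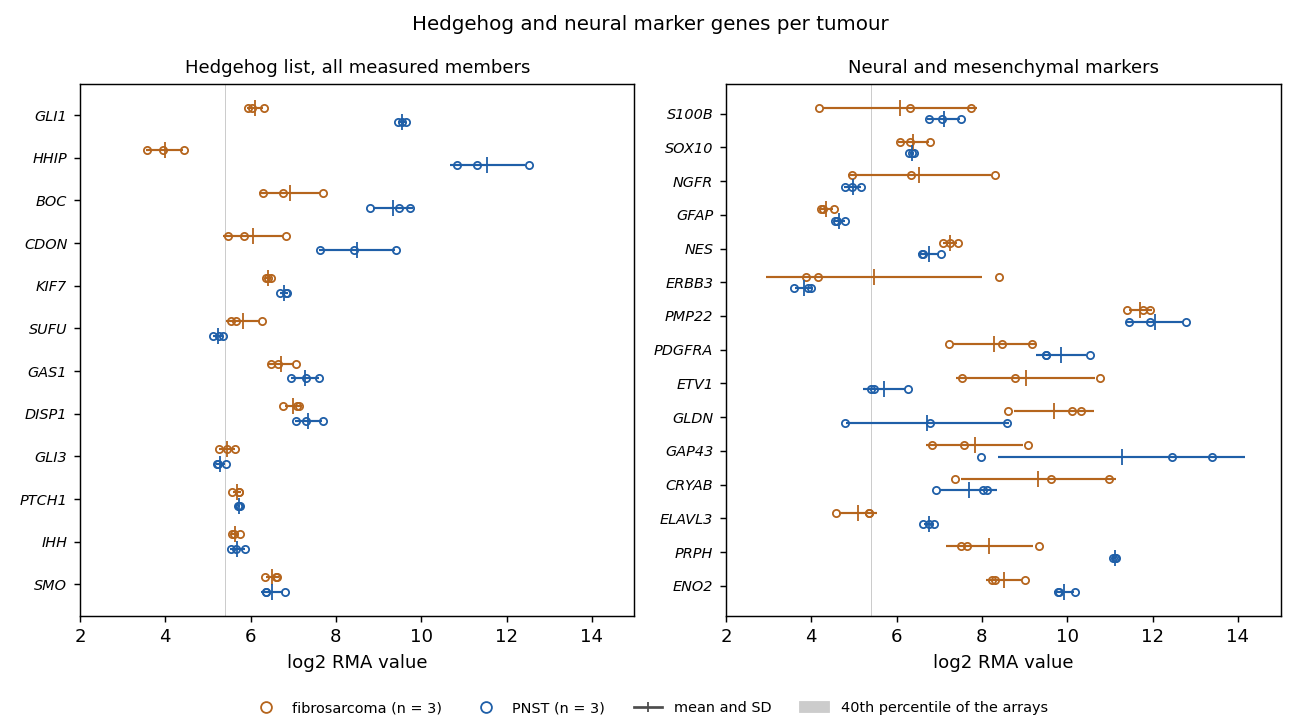
Log2 RMA value (horizontal axis) of the 12 measured members of the Hedgehog list and of 15 neural and mesenchymal marker genes, 1 circle per tumour, with bars for the mean and SD of 3 tumours and a grey band for the 40th percentile of the arrays. *GLI1*, *HHIP* and *PRPH* part the tumour types, while *S100B*, *SOX10* and *PMP22* overlap.

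Lists of other cells of the nerve sheath and of connective tissue did not shift as wholes. Of 9 measured members of the perineurial list, each taken by its brightest probe set, 0 passed in limma and 2 had an unadjusted p under 0.05 (median 0.04, mean -0.10; adjusted p = 0.81, 0.91 with an estimated correlation). When adjusted over the list alone 1 fell and 0 rose. Its members with the smallest p were *SLC2A1*, the glucose transporter GLUT1, at -2.49 (adjusted p = 0.064), *TJP1* at -0.63 (adjusted p = 0.16), *CAV1* at 0.53 (adjusted p = 0.37) and *CLDN1*, claudin-1, at 1.67 (adjusted p = 0.44). Of 2 further *SLC2A1* probe sets, at -3.355 and -2.63, 1 passed the threshold over all probe sets. Of 15 measured members of the pericyte and vascular wall list, 3 fell and 0 rose (3 fell and 1 rose when adjusted over the list alone). *ANGPT1*, angiopoietin-1, fell at least 2.79-fold (adjusted p = 0.013), *GUCY1B1*, a guanylate cyclase subunit, 5.82-fold (adjusted p = 0.046) and *MCAM*, the adhesion molecule CD146, 3.24-fold (adjusted p = 0.049), although 1 of 4 further *MCAM* probe sets differed by 0.01. *NDUFA4L2* differed by 1.36 (adjusted p = 0.056). The pericyte list's shift did not pass (adjusted p = 0.072; 0.50 with an estimated correlation), but did without fibrosarcoma 3 (adjusted p = 0.0099). None of these 3 genes passed without PNST 2 or without PNST 3 (adjusted p up to 0.14). Of 37 measured members of the fibrillar collagen and fibroblast matrix list, 2 rose, 1 fell and 34 did not pass (4 rose and 2 fell when adjusted over the list alone). Besides *CLEC3B*, *DCN*, the proteoglycan decorin, rose 2.57-fold (adjusted p = 0.043), and *LUM*, the related lumican, fell 7.27-fold (adjusted p = 0.012), while *OGN* differed by -1.15 (adjusted p = 0.060). *LUM* was lost without PNST 3 (adjusted p = 0.056), and *DCN* without fibrosarcoma 2 or any one PNST (adjusted p up to 0.13). That list's shift did not pass (median 0.23; adjusted p = 0.33, 0.84 with an estimated correlation). *PDGFRA*, a growth factor receptor of fibroblasts, differed by 1.56 (adjusted p = 0.16).

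Part of the genes of cell division fell in PNST. Of 28 measured members of the mitosis and proliferation list, 6 fell, 0 rose and 22 did not pass, and 20 fell when adjusted over the list alone. *KIF23*, a kinesin of cytokinesis, fell 3.41-fold (adjusted p = 0.034), *DLGAP5*, a spindle protein, 3.79-fold (adjusted p = 0.038), *PLK1*, a mitotic kinase, 2.69-fold (adjusted p = 0.037) and *CDC20*, an activator of the anaphase-promoting complex, 2.68-fold (adjusted p = 0.036). The median difference was -1.43, and 26 of the 28 members were lower in PNST (adjusted p = 4.4e-10 in camera; 0.50 with an estimated correlation and 0.078 in fry). The list's mean level was 8.12 in fibrosarcoma 2, against 9.09 and 8.95 in the other fibrosarcomas and 7.24 to 7.65 in PNST. Each of the 4 genes passed only without fibrosarcoma 2 and in no other fit that left out 1 array, with adjusted p up to 0.13. Of 30 measured members of the DNA replication list, 0 passed in limma, also when adjusted over the list alone, while 4 had an unadjusted p under 0.05 and 24 were lower in PNST (median -0.36; adjusted p = 0.013, 0.78 with an estimated correlation and 0.40 in fry). *RRM2*, a subunit of ribonucleotide reductase, differed by -1.17 (adjusted p = 0.057), *ORC1* by -1.11, *FEN1* by -1.07 and *GINS1* by -0.86 (adjusted p = 0.14 to 0.20). That shift was lost without fibrosarcoma 1 (adjusted p = 0.15), fibrosarcoma 3 (0.093) or PNST 1 (0.089).

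Part of the antigen presentation genes fell in PNST, and of the macrophage genes 1. Of 19 measured members of the antigen presentation list, 6 fell, 0 rose and 13 did not pass, and 12 fell when adjusted over the list alone. *CD74*, the invariant chain of class II molecules, fell 4.68-fold (8.10 ± 0.37 against 10.33 ± 0.56, n = 3 each; adjusted p = 0.025), *DLA-DRA*, a class II chain, 2.64-fold (adjusted p = 0.035), *TAP1*, a peptide transporter, 3.85-fold (adjusted p = 0.036) and *DLA-DMB* 2.67-fold (adjusted p = 0.038), although 1 of 2 further *TAP1* probe sets differed by only -0.34. *CD74*, *DLA-DRA* and *DLA-DMB* passed only without fibrosarcoma 1, and *TAP1* only without fibrosarcoma 2 or fibrosarcoma 3, among the fits that left out 1 array (adjusted p up to 0.13). The list's median difference was -1.40 (adjusted p = 3.1e-06 in camera; adjusted p = 0.50 with an estimated correlation). Of 25 measured members of the macrophage and myeloid list, 24 were lower in PNST, but *CD74* alone passed, also when adjusted over the list alone (median -0.96; adjusted p = 2.6e-05, 0.56 with an estimated correlation). *CD86*, a costimulatory molecule, differed by -1.33, *FCER1G*, under the background level on 2 PNST arrays, by -0.82 and *AIF1* by -1.23 (adjusted p = 0.11 to 0.12). Of 25 measured members of the interferon response list, 0 passed in limma, also over the list alone, while 6 had an unadjusted p under 0.05 and 22 were lower (median -0.88; adjusted p = 0.0021, 0.78 with an estimated correlation). *OAS2*, an antiviral enzyme, differed by -1.53, *GBP1* by -1.52, *IFI35* by -0.88 and *IFIH1* by -1.59 (adjusted p = 0.083 to 0.13), and the interferon shift was lost without fibrosarcoma 3 (adjusted p = 0.061). The mean level of the macrophage list, 8.85 to 9.82 in fibrosarcoma and 8.12 to 8.77 in PNST, moved with the antigen presentation list only in part. Within each type both were lowest in the tumour numbered 1. Among the fibrosarcomas the macrophage list was highest in fibrosarcoma 2 (9.82), but the antigen presentation list in fibrosarcoma 3 (10.70), as was the interferon list (9.03).

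Feedback genes of the RAS-MAPK pathway fell in part. Of 16 measured members, 4 fell and 0 rose (5 fell when adjusted over the list alone). *DUSP5* fell 6.38-fold (adjusted p = 0.016) and *DUSP6* 5.17-fold (adjusted p = 0.037), both phosphatases of MAP kinases, *IER3* 5.18-fold (adjusted p = 0.017) and *PHLDA1* at least 2.40-fold (adjusted p = 0.035). None of the 4 passed without PNST 2 or without PNST 3 (adjusted p up to 0.12). The list's median difference was -0.88 (adjusted p = 0.0027 in camera; adjusted p = 0.50 with an estimated correlation). Of 14 measured members of the smooth muscle contractile list, 1 fell and 13 did not pass (4 fell when adjusted over the list alone). *ACTA2*, smooth muscle actin, fell 5.92-fold (adjusted p = 0.025), and *TPM2* at -2.66 (adjusted p = 0.051), *MYL9* at -1.42 (adjusted p = 0.058) and *MYLK* at -2.89 (adjusted p = 0.11) did not pass (list median -0.85; adjusted p = 0.0044, 0.45 with an estimated correlation). *ACTA2* was lost without fibrosarcoma 3 or any one PNST (adjusted p up to 0.095). Across the fibrosarcomas the mean level of this list (9.94, 9.26 and 9.68) ranked like that of the skeletal muscle list (7.31, 6.44 and 6.98), with which it shares *DES*. The mitosis list ranked the same way (9.09, 8.12 and 8.95), so an order of 3 arrays cannot tell whether muscle tissue contributed. In PNST the smooth muscle list ran from 8.28 to 8.94, while the skeletal muscle list stayed at 6.64 to 6.66.

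Of 26 measured members of the matrix protease, inhibitor and crosslinking list, 2 rose and 2 fell (3 rose and 6 fell when adjusted over the list alone). *MMP2*, a gelatinase, rose 7.04-fold (adjusted p = 0.019) and *TIMP2*, its inhibitor, 2.38-fold (adjusted p = 0.049), while *P4HA2*, a collagen prolyl hydroxylase, fell 8.61-fold (adjusted p = 0.027) and *PLAU*, urokinase, 4.76-fold (adjusted p = 0.046). Of the other probe sets, 1 of 2 for *MMP2* differed by only 0.15 and 1 of 5 for *P4HA2* by only -0.34. None of the 4 passed without PNST 1 or without PNST 3, and *TIMP2* passed in no fit that left out 1 array (adjusted p of the 4 up to 0.15). The list leaned lower in PNST (median -1.11; adjusted p = 0.033, 0.45 with an estimated correlation), and its shift was lost without fibrosarcoma 1 (adjusted p = 0.070) or PNST 3 (0.074). Of 29 measured members of the hypoxia and glycolysis list, 2 rose and 3 fell (2 rose and 15 fell when adjusted over the list alone). *EGLN3*, an oxygen-sensing prolyl hydroxylase, fell at least 3.25-fold (adjusted p = 0.013) and *ANKRD37* 4.59-fold (adjusted p = 0.036), while *ANGPTL4* rose 2.89-fold (adjusted p = 0.0093) and *ENO2* rose as above. *EGLN3* was lost without PNST 2 or PNST 3 (adjusted p up to 0.059), and *ANKRD37* passed only without fibrosarcoma 1 (adjusted p up to 0.10 otherwise). The list's median was -0.61 (adjusted p = 0.00041 in camera; adjusted p = 0.52 with an estimated correlation). Of 29 measured members of the oxidative phosphorylation list, 0 passed in limma, also over the list alone, while 7 had an unadjusted p under 0.05 and 23 were lower (median -0.25; adjusted p = 0.012, 0.45 with an estimated correlation). *COX4I1* differed by -0.54, *NDUFB8* by -0.50, *CYCS* by -0.88 and *UQCRC2* by -0.55 (adjusted p = 0.070 to 0.098), and that shift was lost without fibrosarcoma 2 (adjusted p = 0.055).

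**Figure D3:**
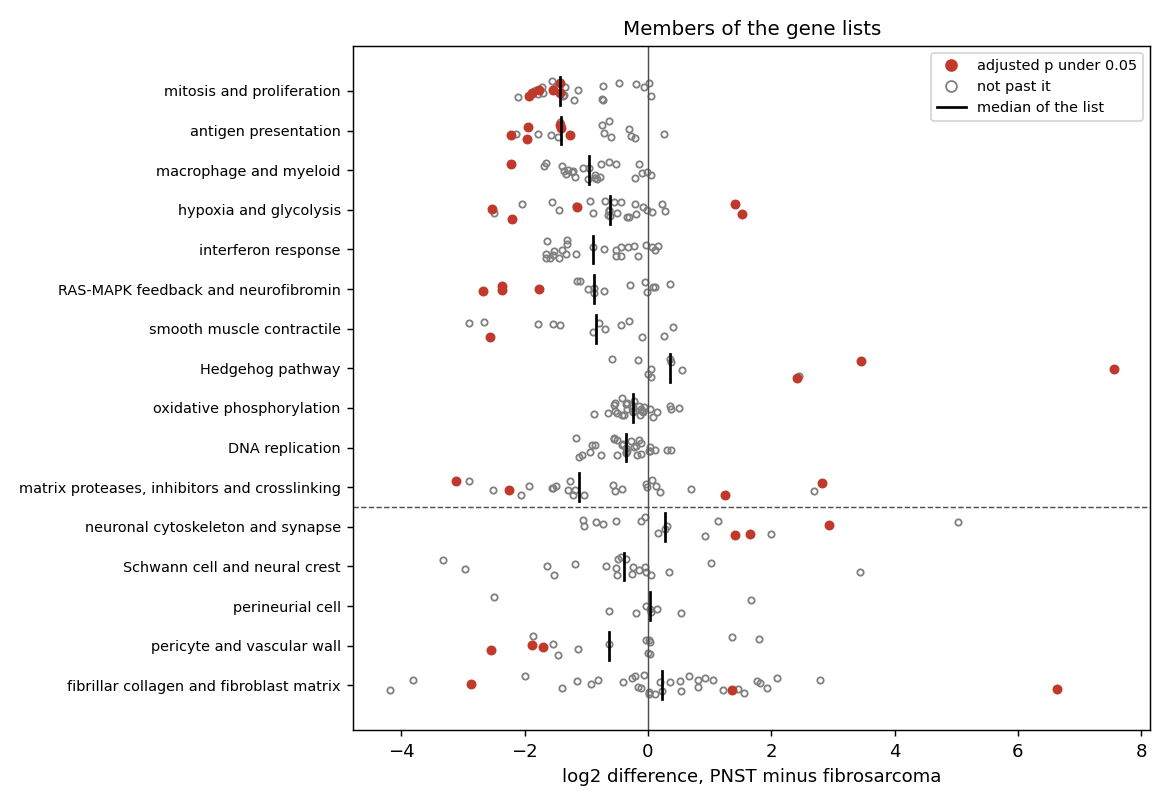
Log2 difference, PNST minus fibrosarcoma (horizontal axis), of each measured member of 16 gene lists, with filled points for members past an adjusted p of 0.05, open points for the others and a vertical bar for each list's median. The 11 lists above the dashed line passed camera with its preset correlation and the 5 below did not, and the Hedgehog median of 0.36 stands far below its 3 filled points.

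In all, 11 of 36 lists tested passed camera with its preset correlation, 10 of them lower in PNST. With a correlation estimated from the 6 arrays 0 passed and 4 had an unadjusted p under 0.05, and 5 passed fry: of the 11, the Hedgehog and oxidative phosphorylation lists (adjusted p = 0.0011 and 0.016), and besides them the neuronal list, adipocytes (0.019, higher in PNST) and B and plasma cells (0.026, lower in PNST). The other 20 lists did not pass camera. Their adjusted p in camera was 0.062 for B and plasma cells, 0.12 for T and NK cells, 0.47 for mast cells, 0.39 for endothelial cells, 0.33 for adipocytes, 0.70 for keratinocytes and skin appendages and 0.93 for melanocytes. It was 0.33 for inflammatory cytokines, 0.33 for receptor tyrosine kinases, 0.34 for housekeeping genes, 0.41 for the unfolded protein response, 0.50 for axon guidance, 0.62 for the TGF-beta and BMP pathway, 0.62 for cartilage and bone and 0.62 for immediate early genes. It was 0.79 for tumour suppressors and oncogenes, 0.81 for the Wnt pathway, 0.85 for basement membrane and 0.96 for the HOX genes. The skeletal muscle list did not shift (median -0.02; adjusted p = 0.78), but its mean level was 7.31 in fibrosarcoma 1, 6.44 in fibrosarcoma 2, 6.98 in fibrosarcoma 3 and 6.64 to 6.66 in PNST, and *ACTA1*, skeletal muscle actin, which fell with an adjusted p of 0.049, read 9.66, 7.44 and 8.37 in the fibrosarcomas and 5.70 to 6.07 in PNST. The list median, mean and camera direction differed in sign for the tumour suppressor, Wnt, perineurial, basement membrane, melanocyte and HOX lists. Of 30 members named from lists and past the threshold, beyond the 24 genes of the first part, 22 kept an adjusted p under 0.05 without fibrosarcoma 1, 16 without fibrosarcoma 2, 13 without fibrosarcoma 3, 7 without PNST 1, 4 without PNST 2 and 2 without PNST 3. *GLI1* and *ANGPTL4* alone kept it in all 6 of these fits.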

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

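Of the tests in this part, those of HHIP and PTCH1 were chosen after the values were seen, as were the comparisons with other splits of the arrays and the intervals of list means, while the other tests of the macrophage and antigen presentation lists were set before.

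The control probe sets, which took no part in the comparison, held a difference between the groups. All 6 control probe sets for GAPDH, a glycolytic enzyme often used as a reference gene, were lower in PNST, by -1.02, -0.87 and -1.05 for the 3', 5' and middle probe sets of one design and by -0.87, -0.90 and -1.02 for those of the other (log2, limma, adjusted p 0.017 to 0.038 over the 111 controls). The difference between 3' and 5' GAPDH probe sets, a measure of RNA length, was 1.22 ± 0.06 in PNST and 1.19 ± 0.23 in fibrosarcoma, and that of actin 1.93 ± 0.45 and 1.90 ± 0.32 (n = 3 each).

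The contrast itself was set against every other way to part the 6 arrays into 3 and 3. The 10 splits are too few for a share under 0.05. The true split alone (1 of 10) gave as many calls as it did, with 1453 probe sets against 0 in the highest other split, 766 higher in PNST and 687 higher in fibrosarcoma against 0, 1965 at least 2-fold apart at an unadjusted p under 0.01 against 120, and 11 shifted lists against 8. A split that mixes the tumour types still holds part of their difference, so its calls are not a count of false ones. The rest of that difference widens the spread within its groups and lowers its calls. The 0 calls of the other splits therefore do not measure what groups without a true difference would give. Those splits nevertheless gave 2 to 8 shifted lists in camera with its preset correlation. The 11 lists of the true split are therefore not far above what mixed groups gave.

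The first pattern weighed is the rise of HHIP, GLI1 and BOC in PNST, 3 of the 12 measured members of the Hedgehog list, whose other 9 did not pass (list median 0.36; adjusted p = 0.0058 in camera, 0.45 with an estimated correlation). A fault of 1 probe set alone is argued against for HHIP, since a second HHIP probe set was higher by 6.47 on the log2 scale (adjusted p = 0.0054 in limma). Probe sequences were not used, so cross-hybridisation common to both HHIP probe sets stays open. GLI1 has a single tested probe set, so that no second one could be compared. The second BOC probe set was higher by only 0.63 against 2.43 and did not pass. A faulty probe set therefore stays open for GLI1 and BOC. Active Hedgehog signalling in the PNST cells may underlie GLI1 and HHIP, both targets of the pathway, but PTCH1, a further target, differed by only 0.0515, and its probe set lay as little as 0.18 above the background level, too dim to decide. Signalling in the tumour cells therefore stays open beside a source in other cells of the specimen, which was not tested.

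The second pattern is the lower mean level of the macrophage and antigen presentation lists in PNST, where 24 of 25 and 13 of 19 members did not pass one by one and neither list passed with an estimated correlation (adjusted p = 0.56 and 0.50). A single fibrosarcoma specimen as the source found no support but is not excluded. Without each fibrosarcoma in turn the mean level was still lower in PNST, by -1.22, -0.73 and -0.82 for macrophages (-0.93 with all arrays) and by -1.33, -1.22 and -0.89 for antigen presentation (-1.15). In camera with its preset correlation neither list's adjusted p exceeded 0.00046 when each fibrosarcoma array was left out in turn, which had been set as the result that would exclude it, but that setting disregards how far the members of a list move together between arrays. Set against the spread between arrays, the 95% interval of the difference lay below 0 for macrophages without fibrosarcoma 1 (-2.06 to -0.39) and included 0 in the other 5 fits, reaching up to 0.59 for macrophages and 0.30 for antigen presentation, with 2 fibrosarcomas left in each. More macrophages in the fibrosarcoma specimens may account for it, which stays open. All 10 of the 10 brightest macrophage list members were lower in PNST, by -0.21 for MRC1 to -1.68 for CD68, but since 24 of all 25 members were lower, at least 9 of any 10 had to be, and the count adds no support. Of the 25 measured members of the macrophage list, 2 are held by another list as well, CD74 and CSF1R, and tumour cells can express class II genes themselves. B cells carry class II genes and CD74 as well, and the B and plasma cell list had a lower mean level in PNST too (6.49 to 6.60 against 7.20 to 7.73; adjusted p = 0.062 in camera, 0.50 with an estimated correlation and 0.026 in fry), so B cells stay open as a further source. Whether macrophages were more numerous or each held more of these transcripts, and whether the tumour cells took part, was not tested.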

How the results depend on the processing

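The 4 counts stayed within 1.5 times their value with no filter, the 60th percentile filter, repeated quantile normalization, median centring, trend and robust settings and array weights. Without moderation the calls were 76 (38 higher in PNST and 38 higher in fibrosarcoma), with 1071 at least 2-fold apart at an unadjusted p under 0.01. Leaving out each array in turn gave 295 to 1240 calls, 150 to 586 higher in PNST and 139 to 654 higher in fibrosarcoma, and 1482 to 2149 at least 2-fold apart, with fewer arrays in each fit. Only 278 to 835 of the calls of these fits were among the 1453 of the main fit. The labels do not say whether the replicate numbers pair the tumours. Tumours of the same number deviated from their group means with correlations of 0.063, 0.018 and -0.025, and those of different numbers with -0.091 to 0.086. These values give no sign of pairing, but 3 arrays per group are too few to exclude it. With the number as a block there were 437 calls, 208 and 229 by direction, and 13 shifted lists.

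With an estimated correlation 0 lists passed and with fry 5, against 11. Leaving out each array gave 10 to 11 in camera, but not always the same lists. Without fibrosarcoma 1, DNA replication (adjusted p = 0.146) and matrix proteases (0.0697) were lost in camera while 11 lists still passed, so others took their place. The adjusted p with an estimated correlation was 0.503 for mitosis, antigen presentation and RAS-MAPK feedback, 0.556 for macrophages, 0.518 for hypoxia, 0.777 for interferon and DNA replication and 0.449 for smooth muscle, Hedgehog, oxidative phosphorylation and matrix proteases. With fry it was 0.0785 for mitosis and for matrix proteases, 0.0727 for antigen presentation, 0.132 for macrophages, 0.125 for hypoxia, 0.361 for interferon, 0.0657 for RAS-MAPK feedback, 0.0897 for smooth muscle and 0.398 for DNA replication, while the neuronal, B and plasma cell and adipocyte lists passed at 0.0265, 0.0265 and 0.0193. Fry asks another question than camera. With no filter 14 lists passed, the 11 and besides them the pericyte list at 0.0217 and the T and NK cell and B and plasma cell lists at 0.0418 each, and the cause was not tested. Leaving out each array, adjusted p ran from 2.1e-07 to 0.0612 for interferon, 0.0091 to 0.0549 for oxidative phosphorylation, 2.4e-05 to 0.146 for DNA replication, 0.0165 to 0.0745 for matrix proteases and 0.0099 to 0.209 for pericytes.

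Of 88 named probe sets, 54 past the threshold, 0 changed direction under any alternative once called. Calls were lost for 49 without moderation, 31 with the block, 18 with no filter, 10 with the mean of a gene's probe sets, 2 with trend and robust settings, 2 with array weights, 0 with either rescaling, and 12 to 38 when 1 array was left out. Signal near the background limits the folds of dim genes, and the 40th percentile is only a stand-in for a detection call.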

Other observations

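Single members stood out in lists that did not shift as wholes. They were chosen after their values were seen and all adjusted p values are from limma. Among axon guidance genes, 2 of 32 measured members rose in PNST, ROBO2 and the ephrin receptor EPHA3 (10.01 ± 0.78 against 5.61 ± 0.15, n = 3 each; adjusted p = 0.0064), and 2 fell, the semaphorin SEMA3A (at least 3.14-fold; adjusted p = 0.018) and the semaphorin receptor PLXND1 (-2.62 on the log2 scale; adjusted p = 0.022). Among 19 basement membrane genes the laminin chain LAMB2 rose by 2.33 (adjusted p = 0.0064), while COL15A1 (-2.41) and HSPG2, perlecan (-1.39), fell. CHRDL1, a BMP antagonist, read 7.99 ± 0.72 in PNST and lay under the background level on every fibrosarcoma array, TGFBI differed by -3.65, and LGR4, a receptor of R-spondins, was higher by 3.15 (adjusted p 0.012 to 0.027). The chemokine CXCL12 read 13.01 ± 0.08 in PNST and 9.95 ± 1.16 in fibrosarcoma (adjusted p = 0.037). MYC was higher by 1.92 and EZH2, a histone methyltransferase, differed by -1.92 (adjusted p = 0.016 and 0.015). Of BANK1 and BLNK, signalling adaptors of B cells, the first was at least 7.11-fold lower and the second differed by -1.08 (adjusted p = 0.026 and 0.030). Of these 14 genes other than ROBO2, 11 passed without fibrosarcoma 1, 10 without fibrosarcoma 2, 11 without fibrosarcoma 3, 5 without PNST 1, 3 without PNST 2 and 5 without PNST 3, and EPHA3 and LAMB2 passed in all 6 of these fits.

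A cluster of neighbouring transporter genes of the ATP-binding cassette family changed in all but one of its measured members. In the reference gene order ABCA5, ABCA6, ABCA9 and ABCA8 lie in 1 stretch of 7 genes, and 4 of these 7 had tested probe sets. ABCA6 was higher in PNST by 4.29 and 3.93 in its 2 probe sets, ABCA9, under the background level on fibrosarcoma 1, by 4.32 and ABCA8 by 4.64 (adjusted p = 0.020 to 0.036, limma). ABCA8 spread widely among the fibrosarcomas (5.43, 8.77 and 6.73), and the ABCA6 probe set at 4.29 among the PNST (10.23, 12.26 and 12.03). ABCA5, at the edge of the stretch, differed by -0.10 and -0.01 in its 2 probe sets (adjusted p = 0.89 and 0.99). Without PNST 2 or PNST 3, none of the 3 genes that rose passed (adjusted p up to 0.13), and without fibrosarcoma 1, fibrosarcoma 3 or PNST 1 the number that passed was 2, 1 and 2. These genes were chosen after their values were seen. Their sequences are related, and shared hybridisation among ABCA6, ABCA8 and ABCA9 was not tested.

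Some tumours stood apart within their type, which the labels do not explain. STMN2 and GAP43, genes of growing axons, read 12.43 and 12.46 in PNST 2 and 12.59 and 13.39 in PNST 3, but 6.09 and 7.98 in PNST 1. Fibrosarcoma 1 held the highest skeletal muscle list mean (7.31), with TNNI2 at 9.82 against 6.95 to 7.90 in the other tumours, and the array weight fitted to it was 0.53 against 0.97 to 1.44 for the others.

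One hypothesis of regional change was set before its result was seen. If long segments of chromosomes differ in copy number between these tumours, differences of genes some places apart along a chromosome should correlate. Over 10190 genes in reference order, the log2 differences of genes 10 places apart correlated at r = 0.0404 across genes, above the highest of 1000 random orders (0.0327), and at 50 places the value was 0.0641 against 0.0395. Each tumour set against the mean of its own type gave 0.0357 to 0.0968 at 10 places, so that neighbouring genes also moved together among tumours of 1 type. Set against the mean of the other type they gave 0.0157 to 0.0726, with fibrosarcoma 2 (0.0157) and PNST 1 (0.0319) under the highest of the random orders. The correlations at 10 and 50 places between the types are what copy-number change would need and are small, and copy number may contribute to the differences. At 1 place apart the correlation was larger, 0.103 against 0.0276 in the highest of the random orders. Shared regulation of neighbouring genes and the base content of probes along chromosomes stay open, since neither was tested.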
